A study of Mus musculus with 10 samples.

How the data were processed

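The samples were primary pancreatic islets of control mice and of mice labelled SIRT6 transgenic, used fresh and without culture per the labels' protocols. Total RNA was taken with the Qiagen RNeasy Plus Mini kit and made into libraries with the Illumina stranded mRNA kit, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.10, STAR 2.7.11a and featureCounts 2.0.0 and the builds GRCm38 and mm10, with no options and no annotation release. The authors deposited 1 table of raw read counts per gene, with Ensembl gene identifiers and 1 column per library. The values were checked to be whole numbers and were read as unnormalised counts. Of the 56262 genes, 55141 were matched to a symbol by identifier (54349 with the version), and the 1121 without one held 0.0211% of the counts. Symbols, gene types and coordinates came from the GENCODE annotation of GRCm38.

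The 10 libraries were grouped by genotype and age from the labels, with 2 libraries per arm at 10 months and 3 per arm at 16 months. The batch of the labels is the same split as age, so no batch term could be entered, and the genotype comparisons lie within a batch. Total counts ran from 32533177 to 92529221 per library, and 23073 to 26108 genes had a count. Xist had 0 to 8 counts and the Y-linked gene Ddx3y 40.1 to 96.3 CPM in every library, so that all libraries were of 1 sex and no sex term was fitted. Replicates were checked for being copies of one another over genes with at least 20 counts in a pair, and none were.

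The test was edgeR 4.0.16 in R 4.3.3, a quasi-likelihood F test with robust dispersions on the counts, TMM scaling (factors 0.761 to 1.21) and the filterByExpr filter on the groups, which kept 19218 genes. All 10 libraries entered 1 fit with a mean per group. The contrasts were labelled transgenic minus control at 10 months, at 16 months, averaged over the ages, the difference at 16 months minus that at 10 months, and 16 minus 10 months within each genotype. A call was a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error was that of the log2 fold change, and intervals are 95% intervals, which cover the spread between libraries.

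For gene groups, 31 lists with 558 genes (547 tested) were fixed, as were the comparisons, the tests, the alternatives and the rule for named genes, before the data were examined. The lists covered beta cell identity and function, insulin granule exocytosis, disallowed genes with dedifferentiation, endoplasmic reticulum stress, oxidative phosphorylation, glycolysis and HIF1 targets, cholesterol synthesis, ribosomal proteins, antioxidant genes, apoptosis, senescence and its secretory genes, cell proliferation, DNA repair, NF-kB targets, interferon response and antigen presentation, and sirtuins. Cell type lists covered alpha, delta, PP, acinar, duct, endothelial, stellate, Schwann, adipocyte and red blood cells, lymphocytes and macrophages. Lists of sex-linked genes, of the mitochondrial genome and of immediate early genes served as checks of the samples. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over the 31 lists, and again with an estimated correlation and with fry. camera compares a list with the other genes, while fry asks whether its genes move one way on balance. For each list the members called over all genes, and adjusted over the list alone, were counted. Mean list scores were compared by exact two-sided permutation.

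Named genes were Sirt6, the other sirtuins and the hormone genes. Where genes passed the threshold, the 10 (genotype) or 5 (other comparisons) with the largest change in each direction were taken, with an average log2 CPM of at least 1. Where none passed, the 5 with the smallest p in each direction were taken. Up to 4 called members of each list, or the 2 with the smallest p, were added. Predicted genes, pseudogenes and the variable, diversity and joining segments of immunoglobulins and T cell receptors were counted but not named. Immunoglobulin constant genes such as Ighg3 could be named. Bcl2, Bid, Il1a, Ccl5, Trp53 and Ccr7, and the general leukocyte genes, were named after their values were seen.

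The alternatives were DESeq2 1.42.0, RLE scaling, total count scaling, limma-voom with sample quality weights (weights 0.467 to 2.06), no filter, a stricter filter (CPM of at least 1 in at least 5 libraries), the replicate number as a block (within each age for genotype, across the ages for age), the mean acinar list level as a covariate, an additive model, each age or genotype fitted alone, and leaving out each library in turn. Pairing by replicate number was checked from the residuals of each library after its group mean. At 16 months the correlations of libraries with the same number were 0.276, 0.242 and 0.186, and those of other pairs ran from -0.241 to 0.00668. The blocked value is therefore given beside a result where it changes the call. The labels do not say whether equal numbers mark islets handled together, and the check used these same data. Deviations within a group cancel, so positive values at equal numbers pull those of other pairs down, and the 2 sets are not independent. The pairing is thus an assumption. At 10 months the same correlation was -0.0986 and that of other pairs 0.0986, which did not show pairing. With 2 libraries per arm these values mirror each other by design, while their sign and size were measured. The genotype block still paired the 10-month libraries, which enter the averaged and interaction values with pairs. For age the block joined equal numbers across the ages, a link that no label or check gives.

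The pipeline was tested on simulated data with the same group sizes and depths. Each gene was drawn independently, with the same dispersion in every library and no pair effect. For 4-fold and 2-fold changes edgeR recovered 68.7% and 27.6% at 10 months, 78.8% and 45.9% at 16 months, 86.9% and 53.1% averaged over the ages, and 57.0% and 9.28% for the interaction. For the age comparison it recovered 75.5% and 29.9% in control and 69.4% and 33.0% in labelled transgenic libraries. The transgene itself, the reads and the alignments were not analysed here.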

Results

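Messenger RNA of freshly isolated mouse pancreatic islets was sequenced from control mice and from mice labelled SIRT6 transgenic, at 10 and at 16 months of age. SIRT6 is an NAD-dependent deacylase of chromatin, and the series asks how it bears on the survival and function of beta cells in aging. The 10 libraries fell into 4 groups, with 2 libraries per genotype at 10 months and 3 per genotype at 16 months. The 10-month libraries formed the first batch and the 16-month libraries the second, so age and batch cannot be told apart. The total counts at 10 months were 32533177 and 92529221 in the control libraries and 38815550 and 35026862 in the labelled transgenic libraries. At 16 months they were 52360334, 35990145 and 40010472 in the control libraries and 55051016, 42797397 and 45454219 in the labelled transgenic libraries. Of 56262 genes in the table, 19218 passed the filter on low counts and were tested. Levels are given as CPM (counts scaled to a common library total) after TMM scaling, as mean ± SD over the libraries of a group, and differences as log2 fold changes from edgeR with their standard error (SE).

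Sirt6 (ENSMUSG00000034748.16, a protein-coding gene on chromosome 10, GRCm38 positions 81621785 to 81627797) was read at the same level in both genotypes. Its level was 10.9 ± 1.48 CPM in control and 10.4 ± 0.224 CPM in labelled transgenic islets at 10 months (n = 2 each), and 7.39 ± 0.421 against 7.37 ± 0.846 CPM at 16 months (n = 3 each). Averaged over the ages the ratio of labelled transgenic to control was 0.977, with a 95% interval from 0.823 to 1.16 (log2 fold change -0.03, SE 0.11, adjusted p = 0.941). Each library held 269 to 907 Sirt6 counts. The genotype groups below are therefore those of the labels, since no gene in the table showed the transgene. The related genes Sirt1, Sirt2, Sirt3, Sirt4, Sirt5 and Sirt7 differed by -0.32 to 0.23 on the log2 scale at either age, and none passed the test.

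The islet hormone genes did not pass the test at either age. Ins1 and Ins2, the mouse insulin genes, whose reads are partly alike so that their split is uncertain, went opposite ways. The log2 fold change of Ins2 was 0.45 (SE 0.38, adjusted p = 0.738) at 10 months and 0.48 (SE 0.31, adjusted p = 0.704) at 16 months. That of Ins1 was -0.36 (SE 0.30, adjusted p = 0.733) and -0.21 (SE 0.24, adjusted p = 0.872). Gcg, the glucagon gene of alpha cells, gave -0.19 (SE 0.30) and -0.24 (SE 0.24). Sst, the somatostatin gene of delta cells, gave 0.01 (SE 0.31) and -0.01 (SE 0.25), and Ppy, the pancreatic polypeptide gene, gave -0.05 (SE 0.59) and -0.24 (SE 0.48). Ins2 alone held 11.6% to 22.3% of the counts of a library.

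**Figure D1:**
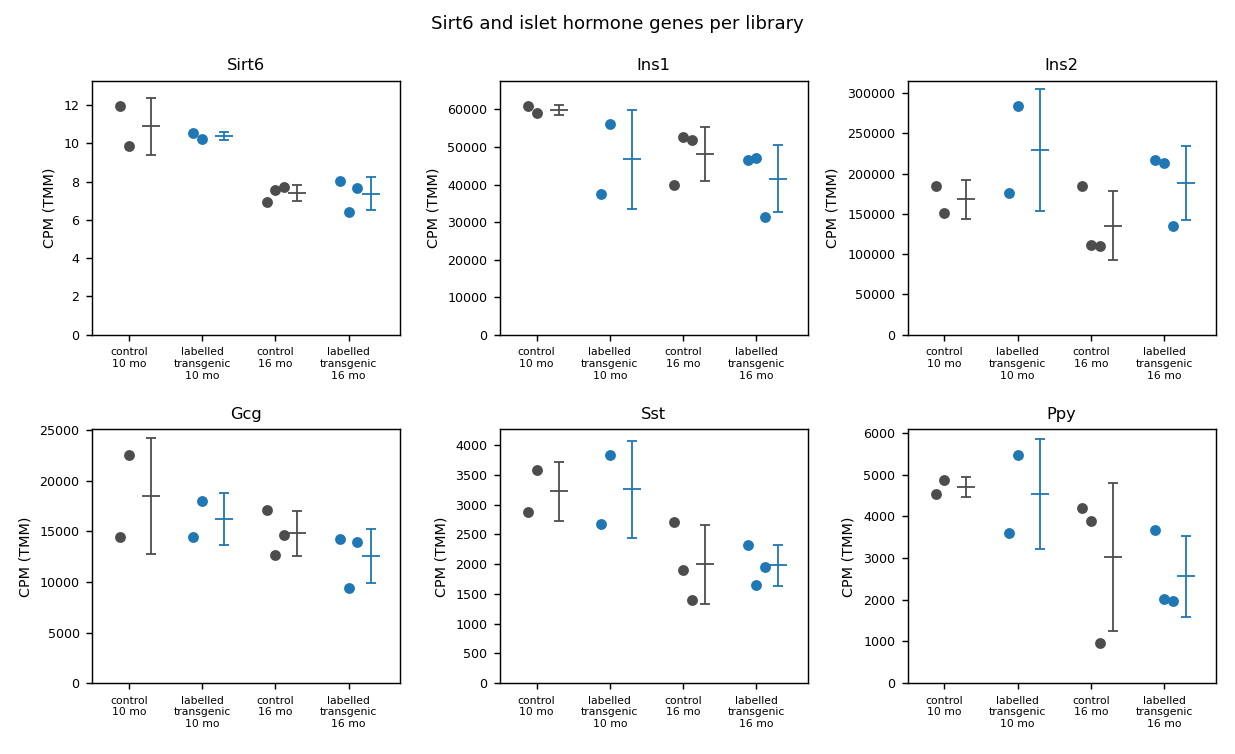
Level of Sirt6 and of the hormone genes Ins1, Ins2, Gcg, Sst and Ppy in CPM after TMM scaling (vertical axes) in the 4 groups of genotype and age, with points for libraries and bars for the mean ± SD. Sirt6 lay at 10.9 and 10.4 CPM at 10 months and at 7.39 and 7.37 CPM at 16 months in control and labelled transgenic islets.

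The comparison at 10 months asked how islets of the 2 genotypes differed before the later age. Genes of exocrine acinar cells were higher in both labelled transgenic libraries than in both control libraries. All 35 measured members of the acinar list were higher, by 1.96 on the log2 scale at the median (range 0.40 to 3.17), and the list was called (adjusted p = 2.33e-22, and adjusted p = 0.775 with an estimated correlation). Adjusted over the list alone, 31 of the 35 rose and 4 were not called, while over all genes tested none passed. Reg1, a secreted product of acinar cells, stood at 566 ± 244 CPM in control and 2643 ± 725 CPM in labelled transgenic islets (log2 fold change 2.22, SE 0.68, n = 2 each). Ctrc, a pancreatic protease gene, stood at 9.30 ± 4.08 against 40.0 ± 14.2 CPM (2.12, SE 0.67). The acinar list held 2.97% to 6.07% of the counts in the control and 13.4% to 15.9% in the labelled transgenic libraries of that age.

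The other 6 lists called at 10 months were also higher in labelled transgenic islets, each with adjusted p = 0.775 with an estimated correlation. Ribosomal proteins were higher by 0.42 at the median (adjusted p = 2.98e-10), with 30 of 30 members higher. Cell proliferation genes were higher by 0.62 (adjusted p = 1.55e-06, 18 of 20 members), among them the cyclin genes Ccna2 (1.10, SE 0.31) and Ccnb1 (1.39, SE 0.42). Genes of oxidative phosphorylation, the mitochondrial respiratory chain, were higher by 0.29 (adjusted p = 4.38e-06, 33 of 34 members), and lymphocyte genes by 0.87 (adjusted p = 0.00916, 19 of 21 members). Genes normally silenced in mature beta cells ("disallowed" genes) were higher by 0.39 (adjusted p = 0.00996, 19 of 24 members). Genes of endoplasmic reticulum stress were higher by 0.19 (adjusted p = 0.0364), a direction that turned to -0.06 under total count scaling. That scaling shifted the median of all genes by -0.24, so the turn is not particular to this list. No member of these 6 lists passed, whether over all genes or adjusted over the list alone. Without labelled transgenic replicate 2 of that age, where its arm holds 1 library that is assumed to vary like the others, the medians were 0.10 for ribosomal proteins, 0.03 for oxidative phosphorylation and -0.04 for lymphocyte genes. The disallowed (0.23) and stress (0.07) calls were lost there as well, which left 2 lists called, the acinar and the proliferation list. The disallowed (0.53) and stress (0.29) calls were also lost without replicate 1 of that group, and the lymphocyte (0.69) and stress (0.06) calls without control replicate 1. With the acinar list as a covariate the disallowed genes turned to -0.25, and the calls of the lymphocyte (-0.00) and stress (0.03) genes were lost, while the other 3 calls held. The mean acinar log2 CPM was 8.08 and 7.09 in the control and 9.36 and 9.83 in the labelled transgenic libraries. The covariate thus largely followed genotype at this age, and these values cannot separate exocrine tissue from genotype.

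No single gene passed the test at 10 months by edgeR at an adjusted p under 0.05, and 1189 genes had an unadjusted p under 0.05, 640 of them higher, where 960.9 would do so by chance. The smallest p-values belonged to genes at an adjusted p of 0.701. On the higher side these were Ahcy, which breaks down S-adenosylhomocysteine (43.1 ± 6.50 against 86.3 ± 2.96 CPM, log2 fold change 1.00, SE 0.17), and Rgs2, a regulator of G protein signalling (1.56, SE 0.28). Mdm1 (0.73, SE 0.13) followed, with the HSP90 co-chaperone genes Ahsa1 (1.14, SE 0.21) and Ahsa2 (1.40, SE 0.26). On the lower side they were the cyclic AMP phosphodiesterase Pde7b (-0.92, SE 0.18), the receptor Gprc6a (-1.41, SE 0.29), Chp2 (-1.18, SE 0.27), the chemokine Ccl28 (-1.26, SE 0.29) and Osbpl5 (-0.62, SE 0.14). In each of these genes, which were picked for a small p, both labelled transgenic libraries lay on one side of both controls. The same was so for 33.3% of all genes tested, where chance gives 33.3%. DESeq2 called 22 genes, edgeR without a filter 6 and limma-voom 0. Leaving out labelled transgenic replicate 1 gave 1895 genes, 565 of them higher, with the lone library of its arm assumed to vary like the others.

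The comparison at 16 months asked how the genotypes differed in older islets. Genes of lymphocytes and of dividing cells were lower in all 3 labelled transgenic libraries. The lymphocyte list was lower, at a median log2 fold change of -2.86 (range -3.40 to -1.13) in 21 of 21 members (adjusted p = 4.52e-17, and adjusted p = 0.294 with an estimated correlation). By fry it was not called (adjusted p = 0.0738). Adjusted over the list alone, 20 of the 21 fell, all but Ccr7. Cd22, a B cell receptor inhibitor, stood at 36.0 ± 19.3 CPM in control and 4.96 ± 2.25 CPM in labelled transgenic islets (n = 3 each, log2 fold change -2.86, SE 0.50). Cd4, the helper T cell coreceptor, stood at 17.1 ± 8.42 against 2.73 ± 1.70 CPM (-2.65, SE 0.53). The proliferation list was lower, at -1.44 (range -1.96 to -0.25) in 20 of 20 members (adjusted p = 1.49e-20, and adjusted p = 0.254 with an estimated correlation), and 18 fell adjusted over the list alone. Mki67, the marker of dividing cells, stood at 19.1 ± 5.51 against 5.49 ± 1.38 CPM (-1.80, SE 0.27), and Ccna2 at 5.66 ± 0.942 against 1.91 ± 0.391 CPM (-1.57, SE 0.24). General leukocyte genes outside the list were lower as well, at -2.42 at the median in 14 of 14 genes.

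Inflammatory groups were lower together with the lymphocyte genes at 16 months. Targets of the transcription factor NF-kB were lower, at -0.94 at the median (18 of 18 members, adjusted p = 2.42e-12, and adjusted p = 0.254 with an estimated correlation), and 13 fell adjusted over the list alone. Among them Nfkbia, the feedback inhibitor of NF-kB, stood at 50.9 ± 7.25 against 30.1 ± 1.18 CPM (log2 fold change -0.76, SE 0.12), and Bcl3 gave -0.95 (SE 0.18). Interferon response and antigen presentation genes were lower, at -0.55 (24 of 26 members, adjusted p = 9.9e-10, and adjusted p = 0.254 with an estimated correlation), and 13 fell adjusted over the list alone. Examples were Psmb9, an immunoproteasome subunit, at -1.04 (SE 0.19) and the peptide transporter Tap1 at -1.03 (SE 0.19). Macrophage genes were lower, at -0.63 (17 of 17 members, adjusted p = 3.22e-05, and adjusted p = 0.618 with an estimated correlation), with Itgam at -1.30 (SE 0.42) and Aif1 at -1.01 (SE 0.33), neither of which passed. Apoptosis genes were lower, at -0.30 (adjusted p = 0.000128, and adjusted p = 0.254 with an estimated correlation), and 3 of 20 fell adjusted over the list alone. These were Bcl2, which restrains cell death (-1.27), and the promoters of cell death Bid (-0.61) and Pmaip1 (-1.90, SE 0.36). Senescence and secretory genes were lower, at -0.65 (adjusted p = 0.000202, and adjusted p = 0.565 with an estimated correlation), and 5 of 21 fell adjusted over the list alone. They were the cytokine genes Il1a, Il1b and Ccl5, the urokinase receptor Plaur and the tumour suppressor Trp53. Control replicate 2 carried most of this, with a mean log2 CPM of 3.13 against 1.87 and 1.69 in the other controls and 1.40 to 1.68 in the labelled transgenic libraries. Without it the median was -0.22 for senescence genes (adjusted p = 0.0270) and -0.25 for macrophage genes (adjusted p = 0.00731). Ribosomal proteins were lower, at -0.30 in 30 of 30 members (adjusted p = 5.5e-07, and adjusted p = 0.727 with an estimated correlation), such as Rps16 (-0.42, SE 0.15), and none passed.

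Beta cell genes were slightly higher in the labelled transgenic islets at 16 months. The list of beta cell identity and function was higher by 0.18 at the median in 28 of 30 members (adjusted p = 1.29e-05, and adjusted p = 0.481 with an estimated correlation), and none of its members passed over all genes or adjusted over the list alone. Leukocyte markers moved with it, as the mean log2 CPM in control replicates 1, 3 and 2 was 9.10, 8.97 and 8.72 for beta cell genes, in the order in which lymphocyte genes rose from 3.21 to 5.45, with beta cell genes at 9.13 to 9.15 in the labelled transgenic libraries. Mafa, a transcription factor of mature beta cells, stood at 405 ± 56.5 against 525 ± 38.6 CPM (log2 fold change 0.37, SE 0.15), and G6pc2, the islet glucose-6-phosphatase, at 1284 ± 109 against 1767 ± 330 CPM (0.46, SE 0.18). Genes of insulin granule exocytosis were higher by 0.20 (18 of 20 members, adjusted p = 9.37e-05, and adjusted p = 0.476 with an estimated correlation). Endoplasmic reticulum stress genes were higher by 0.16 (adjusted p = 0.000799, and adjusted p = 0.653 with an estimated correlation), with Wfs1, the wolframin gene, at 0.38 (SE 0.11), and the call was lost without control replicate 3 (median 0.10). Genes of oxidative phosphorylation were higher by 0.11 (adjusted p = 0.00305, and adjusted p = 0.797 with an estimated correlation), a call lost without control replicate 3 (0.06) or labelled transgenic replicate 1 (0.06) or 2 (0.07). The disallowed genes were lower, at -0.75 (adjusted p = 0.000128, and adjusted p = 0.618 with an estimated correlation), and 10 of 24 fell adjusted over the list alone. Without control replicate 2 the median was -0.11 for disallowed genes, 0.08 for beta cell genes and 0.10 for exocytosis genes, and these calls held. Of the disallowed genes Ldha, lactate dehydrogenase, stood at 46.0 ± 18.7 against 18.9 ± 2.83 CPM (-1.28, SE 0.29), with Zfp36l1 at -1.33 (SE 0.31). Immediate early genes, which respond to tissue handling, were lower, at -0.67 (adjusted p = 0.00497, and adjusted p = 0.797 with an estimated correlation), with Klf6 at -1.06 (SE 0.36) and Hspa1b, whose reads are shared with its copy Hspa1a, at -0.82 (SE 0.26). This call was lost without control replicate 1 (-0.26) or 2 (-0.47), or labelled transgenic replicate 3 (-0.53). The acinar list, at 3.20% to 11.6% of counts in control and 2.79% to 8.39% in labelled transgenic libraries, did not pass (0.04, adjusted p = 0.182). It was called without control replicate 2 (0.89, adjusted p = 1e-10), without labelled transgenic replicate 1 (0.41, adjusted p = 3.52e-07) and with total count scaling (adjusted p = 0.00864). No call was made for the alpha cell (-0.11, adjusted p = 0.589), delta cell (-0.01, adjusted p = 0.892) or PP cell (-0.25, adjusted p = 0.474) lists. The delta cell list was higher by its test and lower by its median.

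**Figure D2:**
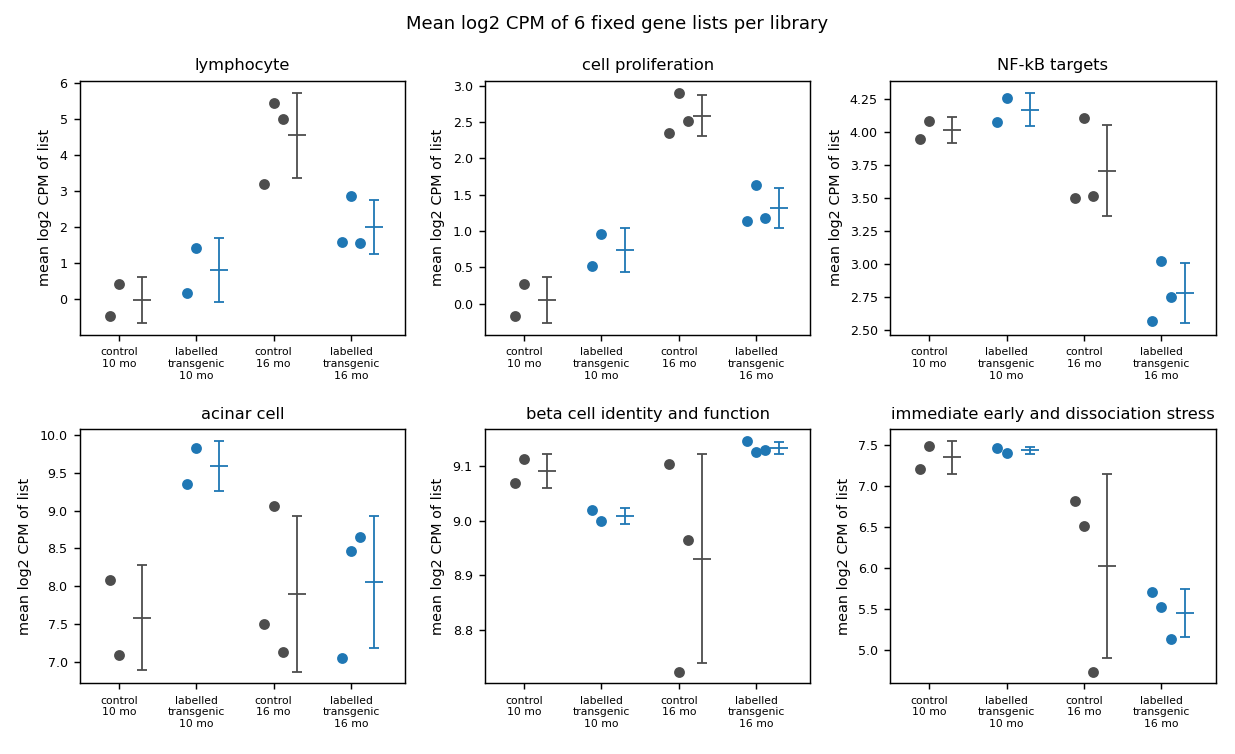
Mean log2 CPM over the members of 6 gene lists (vertical axes) in each library, with points for libraries and bars for the mean ± SD in the 4 groups of genotype and age. At 16 months the labelled transgenic libraries lay lower for lymphocyte genes (-2.54) and proliferation genes (-1.27), and at 10 months they lay higher for acinar genes by 2.01.

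No single gene passed the test at 16 months by edgeR at an adjusted p under 0.05, the smallest adjusted p being 0.0675. At an unadjusted p under 0.05 there were 2150 genes, 349 higher and 1801 lower, where chance gives 960.9. With the replicate numbers taken as pairs, which the labels do not state, 288 genes were called, 4 higher and 284 lower. DESeq2 called 879 (31 higher), edgeR without a filter 426 (5 higher), edgeR with total count scaling 352 (1 higher) and limma-voom 222 (4 higher), and 125 genes were shared by the paired edgeR test and limma-voom. On the simulated data at 16 months DESeq2 made 42 wrong calls, edgeR 6, edgeR with pairs 15 and limma-voom 9. Those data had independent genes and no pair effect, so these counts do not measure the errors among the real calls. In 17.8% of the genes the 3 labelled transgenic libraries did not overlap the 3 controls, where chance gives 10%. Genes are not independent, and this share was not computed for other splits, so its spread by chance is not known. Among the lowest p-values, lower in all 3 labelled transgenic libraries, were Pou2af1, a coactivator of B cell genes (35.8 ± 8.90 against 6.12 ± 0.306 CPM, log2 fold change -2.54, SE 0.33, adjusted p = 0.0675 and 0.0241 with pairs), Il9r, a cytokine receptor (-3.20, SE 0.36, 0.0300 with pairs), and Fcgbp (-2.70, SE 0.34, 0.0300 with pairs). The others were Hmgb2, a chromatin protein of dividing cells (-1.27, SE 0.17, 0.0300 with pairs), and Kif18b, a mitotic kinesin (-2.19, SE 0.30, 0.0337 with pairs). Pairing also brought Mki67 (0.0302), Ccna2 (0.0337), Cd22 (0.0307), Cd4 (0.0460), Nfkbia (0.0427), Bcl3 (0.0460), Psmb9 (0.0460), Pmaip1 (0.0300), Zfp36l1 (0.0337) and Plaur (0.0450) past the threshold. The same held for the glycolytic enzyme Hk1 (-0.92, 0.0460) and the duct keratin Krt19 (-1.29, 0.0337). Higher in all 3 labelled transgenic libraries were Dynlt1b, a dynein light chain with near-identical copies so that its own share is uncertain (6.64 ± 0.678 against 13.9 ± 1.57 CPM, 1.07, SE 0.15, adjusted p = 0.0675 and 0.0337 with pairs). So were the potassium channel genes Kcnh5 (1.18, SE 0.27, adjusted p = 0.0868) and Kcnh1 (1.02, SE 0.24, adjusted p = 0.0892 and 0.0499 with pairs). Impdh1 of guanine nucleotide synthesis (0.39, SE 0.09, adjusted p = 0.0892) and Synpr, a synaptic vesicle protein (0.50, SE 0.12, adjusted p = 0.0938) were higher in all 3 as well. Leaving out control replicate 1 gave 955 genes, and leaving out control replicate 3 gave 4. By exact two-sided permutation of the list means, the lymphocyte, proliferation, NF-kB, interferon, apoptosis, ribosomal, senescence and beta cell lists each gave p = 0.1, the smallest that 3 against 3 can give. The other called lists gave exact two-sided p = 0.2 (disallowed), 0.3 (macrophage, exocytosis, endoplasmic reticulum stress and oxidative phosphorylation) and 0.4 (immediate early). This leaves the pairs out of account. Permuted within the pairs, where the smallest possible is 0.25, each called list gave exact two-sided p = 0.25, with its difference on one side in all 3 pairs, except the immediate early list (p = 0.5). The DNA repair, glycolysis, endothelial and sirtuin lists, which were not called, also lay on one side in all 3 pairs (exact two-sided p = 0.25).

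As the mean of the differences at both ages, which need not be alike, 11 lists were called, each with adjusted p = 0.759 with an estimated correlation, and no member of a list passed. The acinar genes were higher by 1.00 at the median in 35 of 35 members (adjusted p = 1.14e-18). The genes of oxidative phosphorylation were higher by 0.18 in 34 of 34 (adjusted p = 2.91e-08) and those of endoplasmic reticulum stress by 0.17 (adjusted p = 6.57e-05). The lymphocyte genes were lower, at -0.90 (21 of 21 members, adjusted p = 6.57e-05), the interferon genes at -0.24 (adjusted p = 0.000111) and the NF-kB targets at -0.36 (adjusted p = 0.000149). Proliferation genes were lower, at -0.28 (adjusted p = 0.000429) and the macrophage genes at -0.34 (adjusted p = 0.00115). Several of these were not common to the ages, since at 10 and 16 months the medians were 0.87 and -2.86 for lymphocyte, 0.62 and -1.44 for proliferation, 0.19 and -0.94 for NF-kB and 1.96 and 0.04 for acinar genes. Apoptosis genes (-0.20, adjusted p = 0.0294, 0.0568 with pairs), red blood cell genes (-1.07, adjusted p = 0.0418, 0.106 with pairs) and senescence genes (-0.50, adjusted p = 0.0418) were also lower. The values with pairs also paired the libraries at 10 months, where the check did not show pairing. The adipocyte list (0.40, adjusted p = 0.0563) was called with pairs (0.0182), with total count scaling (0.000372), and without control replicate 2 at 10 months (0.0153) or control replicate 2 (0.0333) or 3 (0.0398) at 16 months. By exact two-sided permutation of the list means within each age (120 relabellings, smallest possible p = 0.0167), the called lists gave p = 0.05 (apoptosis) to p = 0.45 (proliferation), and none passed after adjustment over the lists (adjusted p = 0.603 or more). Genes higher in the labelled transgenic libraries with the smallest p were Mdm1 (log2 fold change 0.53, SE 0.08), Asb9 (1.32, SE 0.22), the kinase Cdk18 (0.46, SE 0.09), the deadenylase-related circadian gene Noct (0.39, SE 0.08) and Tdh, of threonine breakdown (1.85, SE 0.40). Lower ones were Fcgbp (-1.59, SE 0.28), the interleukin 1 receptor antagonist Il1rn (-1.16, SE 0.21), the early growth response gene Egr3 (-1.36, SE 0.25), Tox2 (-0.86, SE 0.17) and Il9r, which had 0.0331 CPM in labelled transgenic islets at 10 months and is given no fold. All 10 had an adjusted p of 0.659. G6pc2 was higher in all 5 labelled transgenic libraries than in the controls of their age (0.56, SE 0.14, adjusted p = 0.659). No gene passed by edgeR, 1385 had an unadjusted p under 0.05 (491 higher), and DESeq2 called 51, edgeR without a filter 11 and limma-voom 0. Without labelled transgenic replicate 1 at 10 months 933 genes were called (244 higher) and 4 lists, and the 8 calls of lower lists were lost, at medians from -0.15 (proliferation and apoptosis) to -1.01 (red blood cell). Without control replicate 2 at 10 months the apoptosis (-0.13), proliferation (-0.19) and senescence (-0.44) calls were lost. The red blood cell call was lost without control replicate 1 at 10 months (-0.35), control replicate 1 (-1.17) or 3 (-0.70) or labelled transgenic replicate 3 at 16 months (-1.01), and with the acinar covariate (-0.92) or total count scaling (-1.27). The senescence call was lost without control replicate 2 (-0.13) or labelled transgenic replicate 3 (-0.39) at 16 months or with total count scaling (-0.66), and the apoptosis call without labelled transgenic replicate 1 at 16 months (-0.16).

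Whether the genotype difference itself changed between the ages was tested as the difference at 16 months minus that at 10 months. The ages are also the batches. A batch effect alike in both genotypes cancels here, while one that differs between them does not. Proliferation genes differed by -2.29 at the median in 20 of 20 members (adjusted p = 3.99e-19, and adjusted p = 0.479 with an estimated correlation), and 16 fell adjusted over the list alone, with Ccna2 at -2.67 (SE 0.39). Lymphocyte genes differed by -3.67 (21 of 21 members, adjusted p = 1.34e-13, and adjusted p = 0.479 with an estimated correlation), and 17 fell adjusted over the list alone, with Cd22 at -3.73 (SE 0.85). Ribosomal proteins differed by -0.78 (30 of 30 members, adjusted p = 1.34e-13, and adjusted p = 0.564 with an estimated correlation), and 20 fell adjusted over the list alone. NF-kB targets differed by -1.16 (adjusted p = 4.64e-09, and adjusted p = 0.479 with an estimated correlation), with Nfkbia at -0.95 (SE 0.19), and 11 of 18 fell adjusted over the list alone. Acinar genes differed by -1.95 (35 of 35 members, adjusted p = 6.69e-11, and adjusted p = 0.624 with an estimated correlation), none of them passing.

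The disallowed genes (-1.04, adjusted p = 1.04e-05, 5 of 24 falling adjusted over the list alone) had adjusted p = 0.564 with an estimated correlation. The interferon genes (-0.56, adjusted p = 1.22e-05, 5 of 26 falling adjusted over the list alone) had adjusted p = 0.479 with an estimated correlation. Exocytosis genes (0.35, adjusted p = 9.8e-05, and adjusted p = 0.479 with an estimated correlation) and beta cell genes (0.23, 27 of 30 members, adjusted p = 0.000496, and adjusted p = 0.617 with an estimated correlation) were relatively higher at 16 months, with Mafa at 0.65 (SE 0.24). The senescence list (-1.04, adjusted p = 0.0116, and adjusted p = 0.693 with an estimated correlation) and the apoptosis list (-0.21, adjusted p = 0.0144, and adjusted p = 0.479 with an estimated correlation) were called too. So were the endothelial list (0.27, adjusted p = 0.0198, and adjusted p = 0.796 with an estimated correlation) and the immediate early list (-0.78, adjusted p = 0.0317, and adjusted p = 0.844 with an estimated correlation). The macrophage list (-0.45, adjusted p = 0.0517) was called with pairs (0.00813), with total count scaling (0.0158), and without control replicate 2 at 10 months (0.0279) or control replicate 3 (0.000566) or labelled transgenic replicate 1 (0.0253) or 2 (0.0221) at 16 months. With the acinar list as a covariate the acinar (-0.05), beta cell (0.10), senescence (-0.12) and immediate early (-0.67) calls were lost. At 10 months this covariate largely followed genotype, so these losses cannot be put down to exocrine tissue. Without control replicate 1 at 10 months the senescence (-0.99), apoptosis (-0.18), endothelial (0.29) and immediate early (-0.61) calls were lost, and without labelled transgenic replicate 1 at 10 months those of senescence (-1.24), apoptosis (-0.41) and immediate early genes (-0.77). The endothelial call was also lost without labelled transgenic replicate 2 at 10 months (0.22), control replicate 3 at 16 months (0.16) or labelled transgenic replicate 1 (0.24) or 2 (0.24) at 16 months. The immediate early call was lost without control replicate 1 (-0.45) or 2 (-0.61) or labelled transgenic replicate 3 (-0.63) at 16 months, and the senescence call without control replicate 2 at 16 months (-0.37). No gene passed by edgeR, 1759 had an unadjusted p under 0.05 (457 higher), and DESeq2 called 269, edgeR without a filter 69 and limma-voom 0. The smallest p-values were those of Kif18b (log2 fold change -4.90, SE 0.60), Pou2af1 (-4.28, SE 0.58), Uhrf1, a replication-linked chromatin factor (-3.11, SE 0.44), and Mef2b (-4.91, SE 0.72), all at adjusted p = 0.186. On the other side they were those of Dynlt1b (1.33, SE 0.23, adjusted p = 0.289), Gprc6a (1.45, SE 0.37), Ofd1 (0.68, SE 0.17), the potassium channel Kcnb2 (1.39, SE 0.37) and Osbpl5 (0.69, SE 0.19). Leaving out labelled transgenic replicate 1 at 10 months gave 1408 genes (1057 higher), control replicate 1 at 16 months 156 and control replicate 3 at 16 months 1. Across all 19218 genes the genotype differences at the 2 ages were nearly unrelated (Pearson r = -0.0566, Spearman rho = -0.0674), a correlation across genes, which are not independent replicates.

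**Figure D3:**
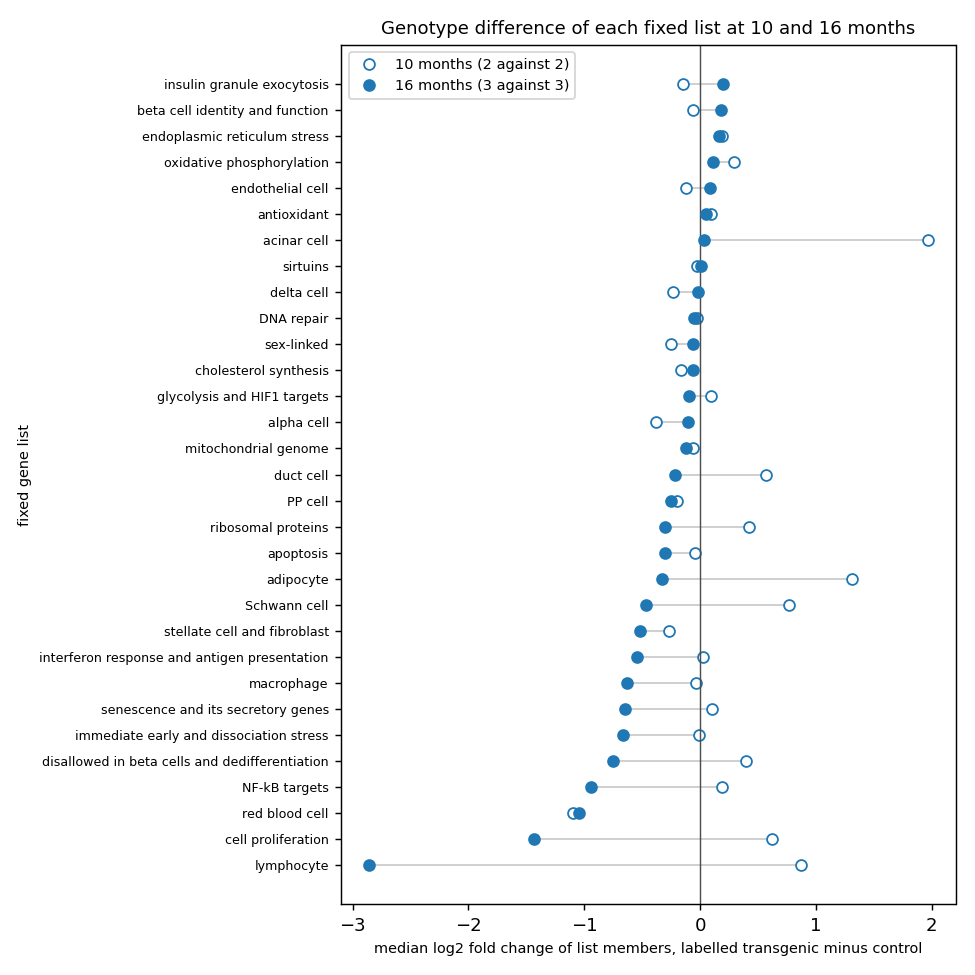
Median log2 fold change of labelled transgenic against control (horizontal axis) over the members of each of the 31 gene lists (vertical axis), with open circles for 10 months (2 against 2 libraries) and filled circles for 16 months (3 against 3). The lymphocyte list lay at 0.87 at 10 months and -2.86 at 16 months, and the acinar list at 1.96 and 0.04.

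In control islets, the comparison of 16 with 10 months asked what changed with age, which is also the change of batch. Lymphocyte and proliferation genes rose most among the lists. The lymphocyte list was higher by 5.21 at the median (adjusted p = 3.16e-12, and adjusted p = 0.615 with an estimated correlation), and 20 of 21 members rose. Among them was Cd22 from 0.947 ± 0.488 (n = 2) to 36.0 ± 19.3 CPM (n = 3, log2 fold change 5.15, SE 0.69, adjusted p = 0.00144), with Cd4 at 5.21 (SE 0.74). The proliferation list was higher by 3.08 (adjusted p = 3.16e-12, and adjusted p = 0.603 with an estimated correlation), and 17 of 20 rose, with Mki67 from 1.06 ± 0.384 to 19.1 ± 5.51 CPM (4.11, SE 0.36, adjusted p = 0.000113). Macrophage genes were higher by 1.52 (adjusted p = 2.67e-06, and adjusted p = 0.700 with an estimated correlation), and 13 of 17 rose, including the chemokine receptor Cx3cr1 (2.91, SE 0.33). Interferon genes were higher by 0.71 (adjusted p = 0.00107, and adjusted p = 0.700 with an estimated correlation), 12 rising, such as the nucleic acid sensor Zbp1 (4.29, SE 0.56), and 2 falling, such as Irf1 (-2.38, SE 0.13). Disallowed genes were higher by 0.67 (adjusted p = 0.0387, and adjusted p = 0.841 with an estimated correlation), 5 rising and 1 falling. That call was lost with the acinar covariate (0.26), with total count scaling (0.81), without control replicate 2 at either age (0.75 at 10 and 0.26 at 16 months), without labelled transgenic replicate 1 (0.62) or 2 (0.62) at 10 months, and without labelled transgenic replicate 3 at 16 months (0.71).

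Cholesterol synthesis and stress genes were lower at 16 months in control islets. The cholesterol list was lower, at -0.68 (adjusted p = 1.61e-06, and adjusted p = 0.603 with an estimated correlation), and 11 of 20 fell, with the synthase Hmgcs1 at -1.65 (SE 0.18, adjusted p = 0.000372) and Fdft1 at -1.08 (SE 0.12). Endoplasmic reticulum stress genes were lower, at -0.18 (adjusted p = 0.00925, and adjusted p = 0.774 with an estimated correlation; 0.0551 with replicate numbers as a block), and 8 fell. Herpud1 fell from 961 ± 59.2 to 175 ± 35.7 CPM (-2.46, SE 0.17, adjusted p = 2.37e-05), and Trib3 (-3.41, SE 0.23) and Chac1 (-3.36, SE 0.30) were among the others. Immediate early genes were lower, at -0.77 (adjusted p = 0.0111, and adjusted p = 0.841 with an estimated correlation; 0.106 with the block), and 5 of 19 fell, with Nr4a1 from 725 ± 65.4 to 70.9 ± 42.0 CPM (-3.35, SE 0.57). Senescence genes were lower, at -1.12 (adjusted p = 0.00302, and adjusted p = 0.767 with an estimated correlation), 10 falling and 4 rising, with the cell cycle inhibitor Cdkn1a at -2.15 (SE 0.17). Antioxidant genes were lower, at -0.26 (adjusted p = 0.0198, 0.0551 with the block), 8 falling and 1 rising, and exocytosis genes at -0.24 (adjusted p = 0.0398, 0.0551 with the block), 3 falling, and these had adjusted p = 0.603 and 0.774 with an estimated correlation. The stellate cell and fibroblast list (0.64, adjusted p = 0.248) was called with the block (0.0118) and without control replicate 3 at 16 months (0.00345). The block joined equal replicate numbers across the ages, which no label or check links. Without control replicate 2 at 10 months the stress call of the endoplasmic reticulum (-0.01) and the exocytosis call (-0.26) were lost, and without control replicate 3 at 16 months these (-0.07 and -0.20) and the immediate early call (-0.34). Exocytosis genes also lost their call without control replicate 2 (-0.12) or labelled transgenic replicate 3 (-0.21) at 16 months, and with the acinar covariate (-0.14) or total count scaling (-0.08).

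In all, 4119 genes changed between the ages, which are also the batches, in control islets, 2171 rising (52.7%) and 1948 falling. The largest rises among genes above the expression minimum were those of Bc1, a short noncoding RNA (ENSMUSG00000115783.1), from 0.0593 ± 0.0390 to 28.3 ± 10.5 CPM (log2 fold change 8.58, SE 0.46, adjusted p = 8.83e-06). Next came the lymphocyte genes Cd8b1 (7.18, SE 1.61, adjusted p = 0.0133), Ighg3 (6.98, SE 1.19, adjusted p = 0.00414), Nkg7 (6.78, SE 1.11, adjusted p = 0.00340) and Ms4a4b (6.65, SE 1.20, adjusted p = 0.00538). The largest falls were those of the AP-1 gene Fosl1, from 18.4 ± 4.46 to 0.0695 ± 0.0795 CPM (-7.87, SE 0.50, adjusted p = 1.79e-05), and of Gpr6 (-5.44, SE 0.76), Mlf1 (-5.34, SE 0.44), and Fhl2 (-4.55, SE 0.23). The stress-responsive factor Maff went from 183 ± 10.4 to 9.99 ± 1.85 CPM (-4.19, SE 0.16, adjusted p = 2.82e-06). Sirt6 fell by 0.56 (SE 0.16, adjusted p = 0.0304). With total count scaling 3422 genes were called, 2485 higher and 937 lower, and the acinar covariate gave 2448. Leaving out control replicate 1 or 2 at 10 months gave 1450 or 1603 genes, with the lone library assumed to vary like the others.

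In labelled transgenic islets, the same comparison of ages showed lower acinar genes, NF-kB targets and stress genes at 16 months. NF-kB targets were lower, at -1.54 at the median (adjusted p = 7.67e-06, and adjusted p = 0.703 with an estimated correlation), and 11 of 18 fell. Nfkbia went from 259 ± 4.52 (n = 2) to 30.1 ± 1.18 CPM (n = 3, log2 fold change -3.11, SE 0.13, adjusted p = 2.57e-06), and Bcl3 fell too (-3.31, SE 0.19). Senescence genes were lower, at -2.15 (adjusted p = 5.77e-05, and adjusted p = 0.703 with an estimated correlation), 13 falling and 1 rising, with Il1b at -3.21 (SE 0.31) and Cdkn1a at -2.71 (SE 0.18). Immediate early genes were lower, at -1.45 (adjusted p = 5.77e-05, and adjusted p = 0.871 with an estimated correlation), and 10 of 19 fell. Acinar genes were lower, at -1.52 in 35 of 35 members (adjusted p = 7.67e-06, and adjusted p = 0.871 with an estimated correlation), and 3 fell. The trypsin inhibitor Spink1 was among them, from 323 ± 85.8 to 64.9 ± 28.5 CPM (-2.31, SE 0.61, adjusted p = 0.0281, 0.0604 with the block). Ribosomal proteins were lower, at -0.57 (adjusted p = 7.67e-06, and adjusted p = 0.871 with an estimated correlation), and 13 of 30 fell, such as Rplp2 (-1.42, SE 0.18). The cholesterol list was lower, at -0.49 (adjusted p = 4.05e-05, and adjusted p = 0.703 with an estimated correlation), 11 falling, with Hmgcs1 at -1.71 (SE 0.18).

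The genes of oxidative phosphorylation (-0.26, adjusted p = 0.00339, 11 falling) and of endoplasmic reticulum stress (-0.16, adjusted p = 0.0455, 0.164 with the block, 9 falling and 4 rising) had adjusted p = 0.871 with an estimated correlation, and their medians turned to 0.07 and 0.17 under total count scaling. The antioxidant genes (-0.26, adjusted p = 0.00722, 7 falling) and the glycolysis genes (-0.29, adjusted p = 0.0182, 5 falling and 1 rising) had adjusted p = 0.703 with an estimated correlation, and their medians turned to 0.07 and 0.05. Total count scaling shifted the median of all genes by 0.32 here, so these turns are not particular to the lists. Macrophage genes were higher by 0.97 (adjusted p = 0.000797), 6 rising and 1 falling, and lymphocyte genes by 1.42 (adjusted p = 0.0182), Jchain alone rising (2.03, SE 0.45). Proliferation genes were higher by 0.60 (adjusted p = 0.0244), 3 rising and 1 falling, with Mki67 from 1.70 ± 0.227 to 5.49 ± 1.38 CPM (1.68, SE 0.33, adjusted p = 0.00781). These lists had adjusted p = 0.871 with an estimated correlation. Without labelled transgenic replicate 1 at 10 months the lymphocyte (0.81) and proliferation (0.28) calls were lost, as they were without labelled transgenic replicate 2 at 16 months (0.88 and 0.41). Without labelled transgenic replicate 2 at 10 months the calls of oxidative phosphorylation (-0.07) and glycolysis (-0.23) were lost. The call of endoplasmic reticulum stress was lost without any 1 of 6 libraries (medians -0.28 to -0.11): both libraries of each genotype at 10 months, control replicate 1 and labelled transgenic replicate 3 at 16 months. With total count scaling the lymphocyte call was lost (1.76). With the block the endothelial (0.25, adjusted p = 0.109, 0.00240 with the block) and stellate (0.35, adjusted p = 0.277, 0.0106 with the block) lists were called as well, the endothelial list also with total count scaling (0.0308) and without labelled transgenic replicate 3 at 16 months (0.00724). Mafa rose from 268 ± 15.1 to 525 ± 38.6 CPM (0.97, SE 0.18, adjusted p = 0.00549), as did Ffar1, a fatty acid receptor of beta cells (1.14, SE 0.23), while the beta cell list did not pass (0.12, adjusted p = 0.464). Sirt7 fell by 0.69 (SE 0.17, adjusted p = 0.0209).

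In all, 3786 genes changed between the ages, which are also the batches, in labelled transgenic islets, 1620 rising (42.8%) and 2166 falling. Bc1 rose from 0.0804 ± 0.00764 to 31.4 ± 4.09 CPM (log2 fold change 8.55, SE 0.49, adjusted p = 9.36e-06), followed by Ighg3 (4.26, SE 1.10), the chemokine receptor genes Ccr2 (3.62, SE 0.46) and Cx3cr1 (3.51, SE 0.35), and Ighg2b (3.58, SE 0.79). Fosl1 fell from 16.9 ± 0.984 to 0.00658 ± 0.0114 CPM (adjusted p = 1.15e-05), too few counts for a fold, and Mlf1 (-6.42, SE 0.48), the stress factor Atf3 (-5.78, SE 0.99), the chemokine Cxcl2 (-5.52, SE 0.76) and Egr4 (-5.40, SE 0.81) fell next. Among genes that rose, 714 were shared between the genotypes, where independence gives 183.0, and among genes that fell 1359 were shared, where it gives 219.6. A batch effect common to both genotypes would be shared in the same way. The age differences of the 2 genotypes were related across genes (Pearson r = 0.663, Spearman rho = 0.668). With total count scaling 4278 genes were called, 3349 higher and 929 lower, limma-voom called 2025 and the acinar covariate 2162. Leaving out labelled transgenic replicate 2 at 10 months gave 1731 genes, and leaving out replicate 1, 2 or 3 at 16 months gave 2404, 2029 or 2365. The labels do not state that each library came from a separate animal, so the p-values of genes measure only the spread between these samples. The list p-values of camera compare a list with the other genes. They do not measure how the list mean varied between libraries. For list means, exact two-sided permutation could give no p under 0.333 at 10 months or under 0.1 at 16 months.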

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

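Chosen after the result was seen were the tests of Sirt6, the acinar covariate as a test of the lymphocyte genes, both tests of the acinar genes and the counts of other splits. For 13 gene lists the difference between labelled transgenic and control islets was not the same at the 2 ages, which are also the batches. This was by a test of the difference itself (16 months minus 10 months). A batch effect that differs between the genotypes cannot be told apart from age here, and no relabelling was run for this test. The medians were -3.67 for lymphocyte genes, -2.29 for cell proliferation, -1.95 for acinar genes, -1.16 for NF-kB targets, -1.04 for disallowed genes, -1.04 for senescence genes, -0.78 for ribosomal proteins, -0.78 for immediate early genes, -0.56 for interferon genes and -0.21 for apoptosis. They were 0.35 for insulin granule exocytosis, 0.27 for endothelial genes and 0.23 for beta cell genes. None of the 13 calls held with an estimated correlation between genes.

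Sirt6 was not higher in the libraries labelled transgenic at either age. Libraries swapped between the groups are argued against as the reason only for a transgene counted at this gene, since the highest control library stood at 1.15 times the median of its age. Whether libraries were swapped is not decided by this value if the transgene was not counted or not expressed. Too few counts are argued against as well, since the upper 95% bound of the fold averaged over the ages was 1.16. What stays open is a transgene whose reads were not counted at the mouse Sirt6 gene, or one that was not expressed. These cannot be told apart here, because 0 entries of the count table lie outside the mouse Ensembl genes.

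Lymphocyte genes were lower in the labelled transgenic islets at 16 months. The median was -2.82 after thinning every library to the smallest total. Thinning keeps the expected share of each gene, so this could not decide on depth. Total counts overlapped between the arms, at 35990145 to 52360334 in control and 42797397 to 55051016 in labelled transgenic libraries. With the acinar covariate the median was -2.85. The acinar list hardly differed between the arms at 16 months (median 0.04, mean score 0.16 higher). Adjusting for it could thus hardly move the lymphocyte median, and exocrine tissue is not decided by it. More leukocytes in the control preparations met their prediction: general leukocyte genes outside the list had a median of -2.42 and 14 of 14 were lower, with Ptprc at 112 against 21.0 CPM, Laptm5 at 114 against 33.4 CPM and Lcp1 at 142 against 37.9 CPM. These cells may have come with lymphoid tissue carried over in the isolation or may have sat within the islets, and a genotype difference in infiltration stays open and untested. The proliferation, NF-kB, interferon, apoptosis, senescence and disallowed lists moved in the same libraries and are not separated from the leukocyte share.

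Acinar genes were higher in the labelled transgenic islets at 10 months. The list median was 1.70 with total count scaling, where the median of all genes was -0.25. Neither TMM scaling nor a shift common to all genes therefore made the rise. Total counts are themselves distorted by a few genes taking most of the counts, so nothing further follows about such genes. More exocrine tissue in those preparations stays open, since the 2 acinar transcription factors measured outside the list, Nr5a2 (1.22, SE 0.52) and Gata4 (0.88, SE 0.55), had a median of 1.05, which passed the bound of 1 by less than its SE. A genotype effect on exocrine cells stays open, as it was not tested.

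Other splits of the libraries were refitted. At 16 months the 10 splits of 6 libraries are too few for a share under 0.05. For genes past the threshold the real count was 0, so that 10 of 10 splits gave as many whatever they held (highest other 1) and nothing follows from it. For an unadjusted p under 0.05 as many came from 1 of 10 (2150, highest other 2096), for lists called 7 of 10 (14, highest other 17), and with pairs 1 of 4 splits that part every pair (288, highest other 0), which are too few as well. Averaged over the ages chance cannot be excluded, with 8 of 60 splits giving as many genes at an unadjusted p under 0.05 (1385, highest other 2305) and 24 of 60 as many lists (11, highest other 16). Nothing follows from 60 of 60 splits giving as many genes past the threshold, since the real count was 0 (highest other 74). The split with 74 genes exchanged control replicate 2 and labelled transgenic replicate 1 at 16 months. That split was the highest of 60 and had 819 genes at an unadjusted p under 0.05, where chance gives 960.9. No cause is read from it, and none was tested.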

How the results depend on the processing

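Each value is the count of genes past the threshold unless a list is named, no alternative was added after the data were seen, and the cause was not tested except where the construction shows it. DESeq2 gave 22 at 10 months, 879 at 16 months, 51 averaged over the ages and 269 for the interaction. No filter gave 6, 426, 11 and 69. At 16 months limma-voom gave 222, total count scaling 352, the replicate block 288, the acinar covariate 1 and the 16-month libraries alone 1, and averaged over the ages the acinar covariate gave 1. For age the acinar covariate gave 2448 in control and 2162 in labelled transgenic islets, and limma-voom 2025 in labelled transgenic islets. Leaving out 1 library gave 0 to 1895 genes at 10 months, 0 to 955 at 16 months, 0 to 933 averaged, 0 to 1408 for the interaction, 1450 to 5098 for age in control and 1731 to 5549 for age in labelled transgenic islets. The Sirt6 differences between genotypes passed under no alternative run.

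With an estimated correlation 0 lists were called in each of the 6 comparisons. fry called 0 at 10 months, 4 at 16 months (proliferation, NF-kB, interferon, apoptosis), 0 averaged, 0 for the interaction and 7 for age in labelled transgenic islets. For age in control islets fry lost the disallowed (adjusted p = 0.231), immediate early (0.237) and exocytosis (0.108) calls. It added the apoptosis (0.0288), DNA repair (0.0451) and sirtuin (0.0270) lists there. Total count scaling gave 12 lists at 10 months, and leaving out 1 library 2 to 10 at 10 months and 4 to 16 averaged. With the acinar covariate at 10 months the disallowed genes turned to -0.25 and the senescence genes to -0.66. The covariate largely followed genotype at 10 months, which bears on its averaged and interaction values as well. The duct list averaged over the ages turned to -0.29, and the acinar list for age in control islets to -0.65, the latter by construction. Leaving out 1 library took the stellate list at 16 months from -1.003 (without labelled transgenic replicate 1) to 0.30 (without control replicate 2), and ribosomal proteins averaged from -0.10 to 0.22 (without labelled transgenic replicate 2 or 1 at 10 months). The correlation of the genotype differences between the ages was -0.123 at an average log2 CPM of at least 3 and -0.145 with each age fitted alone.

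In the remainder, 82 of 113 alternatives kept the gene counts within 1.5 times, 76 of 90 the counts of lists, 9123 of 9723 the side of the threshold of 519 values of named genes (none reversed), and 2465 of 2790 that of the 186 list results. A change of sign was counted as reversed only where the gene or list was called, as reported or in the alternative. Genes called in neither could change sign and still count as kept. The Sirt6 difference averaged over the ages, for example, ran from -0.099 to 0.038 with 1 library left out. A list's direction is that of its test. Total count scaling shifted the median of all genes by -0.24 at 10 months, -0.16 averaged, 0.16 for the interaction, and 0.17 and 0.32 for age in control and labelled transgenic islets. The replicate block also called the adipocyte (0.0170), endothelial (0.0126) and Schwann (0.0452) lists at 10 months, where the check did not show pairing. It changed no list call at 16 months and no count of genes by over 1.5 times elsewhere. A sex covariate was not run, since all libraries were of 1 sex. Depth was at least 32533177 counts and did not limit Sirt6, with 269 counts or more.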

Other observations

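All values in this part were described after the data were seen, from lists fixed before. Several cell types and processes not described above did not pass at 16 months, given as labelled transgenic minus control. Duct cell genes were lower, at a median log2 fold change of -0.21 (adjusted p = 0.378), with Krt19 at 15.1 ± 4.29 against 6.16 ± 2.34 CPM (n = 3 each), and Schwann cell genes at -0.47 (adjusted p = 0.892). Stellate cell and fibroblast genes were lower, at -0.52 (adjusted p = 0.589) and red blood cell genes, the globins, whose copies share reads, at -1.05 (adjusted p = 0.0787). Adipocyte genes gave -0.33 (adjusted p = 0.589), with the test on the higher side, and endothelial genes 0.09 (adjusted p = 0.213). Some of these lists were called with 1 library left out. Red blood cell genes were called without control replicate 1 (adjusted p = 0.0127) or 2 (adjusted p = 0.0127) at 10 months, or control replicate 2 (adjusted p = 0.00421) or labelled transgenic replicate 2 (adjusted p = 0.0305) at 16 months. At 16 months Schwann cell genes were called without control replicate 3 (-0.90), duct genes without labelled transgenic replicate 3 (-0.44), and endothelial genes without control replicate 2 (0.17) or labelled transgenic replicate 3 (0.25). Stellate genes were called without control replicate 2 (0.30) or 3 (-0.93). DNA repair genes gave -0.06 (adjusted p = 0.461), the sirtuins 0.01 (adjusted p = 0.589), antioxidant genes 0.05 (adjusted p = 0.589, with a mean below 0), cholesterol synthesis -0.06 (adjusted p = 0.372), the mitochondrial genome -0.12 (adjusted p = 0.355) and sex-linked genes -0.06 (adjusted p = 0.892). The glycolysis list did not pass (-0.10, adjusted p = 0.453), while adjusted over the list alone 3 of 23 members fell, the hexokinases Hk1 (-0.92) and Hk2 (-1.27) and the lactate dehydrogenase Ldha (-1.28).

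Over all genes the libraries separated by age along the first principal component, which held 53.6% of the variance, with all 10-month libraries between -76.9 and -58.5 and all 16-month libraries between 11.1 and 92.2. Bc1 stood at 0.0317 to 0.0869 CPM in the 10-month libraries and at 22.1 to 40.5 CPM in the 16-month libraries, whatever the genotype. Age and batch cannot be told apart in this change. Median, mean and test did not all share a sign, in lists that were not called, for apoptosis and immediate early genes at 10 months and for 5 lists of the interaction, namely endoplasmic reticulum stress, PP cell, red blood cell, sirtuins and stellate cell. The same was so for glycolysis and sirtuins averaged over the ages, for endothelial and glycolysis genes with age in control islets, and for adipocyte and duct genes with age in labelled transgenic islets.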
